A study of Mus musculus with 6 samples.

How the data were processed

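RNA sequencing was done on RAW264.7 cells, an established mouse macrophage line, kept in high glucose (40 mM) with or without pre-treatment with emetine (5 nM), a plant alkaloid that blocks translation elongation on cytosolic ribosomes. The labels give 3 libraries per group. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made after mRNA isolation, so the data describe mostly polyadenylated transcripts. Per the submitters' processing notes, CASAVA, HISAT2 and StringTie were used and the genome build was GRCm39. Their versions and settings, the annotation release, the counting mode and the handling of strand are not given in the sources used here. Without known strand handling, reads of overlapping and antisense genes cannot be told apart.

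The deposited table holds raw read counts per gene, 1 column per library, which the authors left unscaled for library size. Each column was assigned by the library name in the sample title. The table lists 11183 rows, of which 587 carry only an identifier of an assembled locus with no gene name, and these took between 3.05% and 3.14% of the counts of a library. Each row has a third-highest value above 1 CPM (counts scaled to library size) in the table's own totals, the lowest being 1.004, so genes of low expression had been left out before deposit. A listed gene can therefore be compared, but a gene missing from the table was not analysed here. All rows name a gene or locus, and all were tested. The table gives no coordinates.

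The total was 33533998 counts for high glucose replicate 1 and between 29143967 and 30148348 in each of the other 5 libraries. Pairs of libraries of the same group differed by 5.26 to 15.9 times the sampling noise (chi-square per degree of freedom over genes), so no library was a copy of another. The labels do not say whether replicates were separate cultures. The spread between these samples may therefore be technical, and it is what the p-values of single genes measure. The common biological coefficient of variation was 7.03%.

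Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F-test, 2-sided), emetine against high glucose, with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. The filter removed no row. A positive log2 fold change means higher with emetine. Its standard error (SE) was taken from the fold change and the F statistic, and intervals are 95% intervals from the same fit. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. There were 36 gene lists with 821 distinct genes, of which 628 were in the table. Of these lists, 31 had at least 3 tested genes and were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. Both compare a list with the other genes. With the preset value the genes are taken as almost independent, so that camera p does not measure the spread between libraries. The lists were also tested with fry, which tests a list against no change. Its p is for a shift in a common direction unless mixed directions are named. List counts are given over all genes tested and adjusted over the list alone.

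Genes were named by this rule: Fos, which the study's title names; the 6 largest rises and the 6 largest falls among genes with an adjusted p under the threshold, a symbol, a mean of at least 5 CPM in the higher group and groups that do not overlap; and from each list up to 3 genes with the smallest p among those past the threshold, or else the gene with the highest CPM. Only 1 rise met the rule. Other names were chosen after their values were seen.

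The test was checked on simulated counts with the means and dispersions of these 11183 rows. In 5 draws with 200 changed genes each, it recovered 54% of the genes changed 1.25-fold, 78.8% at 1.5-fold, 94% at 2-fold and 99.2% at 4-fold. Of 950 calls, 6.84% were false. A simulated shift of -0.5 (log2) in the interferon list was called in 5 of 5 draws. The simulation did not include genes that vary together. Each draw held far more changed genes than the 31 called in the real data, which makes the adjusted threshold easier to pass. The interferon list was not counted in the shares recovered. These shares may therefore overstate recovery in the real data.

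The alternatives were other scalings (RLE and upper quartile), other filters, DESeq2 1.42.0, limma-voom, a replicate block, and leaving out each library. Alternatives added after seeing the data left out the unnamed loci or the interferon list, or corrected log2 CPM for transcript length and GC content. For that correction, the length and GC content of the longest protein-coding transcript per symbol came from GENCODE M21, which is on GRCm38, not the build of the counts. A symbol matched for 10384 rows (92.9%). Camera and limma-trend used log2 CPM corrected in each library by a trend over all these rows. Corrected list medians came instead from fold changes with their own trend subtracted. That trend was fitted to genes outside the interferon list or, for the raised lists, outside the raised lists. No coordinate was taken from that annotation. The correction was first run with the longest transcript of any biotype. The definition was changed to protein-coding transcripts after those results were seen, because the first one took a 5024 nt transcript for Akr1b3. The first definition was kept as an alternative, called 13 genes where the second called 16, and gave the lysosome list a camera adjusted p of 0.0475 where the second gave 0.0559.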

Results

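Gene expression was measured by mRNA sequencing in RAW264.7 mouse macrophages held in 40 mM glucose, with 3 libraries from cells without emetine and 3 from cells pre-treated with 5 nM emetine. The depth ranged from 29143967 to 33533998 counts per library over 11183 genes and loci. No library from cells in normal glucose was analysed here, so the single comparison is emetine against no emetine in high glucose. The study's title presents FOS as a marker of diabetic nephropathy and emetine as a treatment, and the comparison measures how RNA levels differed between these groups of libraries.

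Fos, which encodes a subunit of the AP-1 transcription factor, was at the same level in both groups within error. It measured 14.6 ± 1.89 CPM in high glucose and 15.04 ± 1.17 CPM with emetine (SD, n = 3 each). The log2 fold change was 0.04 (SE 0.11, edgeR adjusted p = 0.93), and its 95% interval ran from -0.20 to 0.28. The sign was negative (-0.05 and -0.02) when high glucose replicate 1 or emetine replicate 2 was left out. The AP-1 and immediate early genes, a list that includes Fos and responds to stimuli within minutes, gave no call: over all genes tested by edgeR, 0 of 25 rose, 0 fell and 25 did not pass. Adjusted over the list alone, 2 passed: Atf3, a stress-induced repressor, was at 6.77 ± 0.84 CPM against 9.99 ± 0.79 CPM with emetine (log2 fold change 0.56, edgeR adjusted p = 0.14 over all genes), and Ier3 was at 167 ± 8.08 against 142 ± 6.36 CPM (log2 fold change -0.24, SE 0.05, edgeR adjusted p = 0.13 over all genes, DESeq2 adjusted p = 0.0026). Atf3 was named after its values were seen. Jun and Junb, the partners of Fos, measured log2 fold changes of 0.18 (SE 0.14) and -0.02 (SE 0.08), also chosen after their values were seen. The list's median log2 fold change was -0.12 and its camera adjusted p was 0.30.

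Across all genes, 30 were lower and 1 was higher with emetine at an edgeR adjusted p under the threshold. The changes were small: their absolute log2 fold changes ran from 0.22 to 1.65 with a median of 0.43, and the median fall was 26.3%. The largest named falls were in Paqr5, from 6.93 ± 0.60 to 3.47 ± 0.50 CPM (log2 fold change -0.995, SE 0.15, edgeR adjusted p = 0.041), the antiviral oligoadenylate synthetases Oas3 and Oas2, the large ubiquitin ligase Rnf213, the non-classical MHC class I gene H2-T23, and Scn11a, which encodes a voltage-gated sodium channel. Rnf213 fell from 264 ± 30.7 to 162 ± 6.12 CPM (log2 fold change -0.70, SE 0.08, edgeR adjusted p = 0.016). H2-T23 fell from 106 ± 10.99 to 65.7 ± 6.76 CPM and Scn11a from 21.1 ± 1.497 to 13.1 ± 1.54 CPM. After correction for transcript length and GC content (limma-trend), 3 of the named falls were no longer called: Rnf213 went from -0.695 (SE 0.0741) to -0.545 (SE 0.0964, adjusted p = 0.096), Oas3 from -0.694 (SE 0.0986) to -0.667 (SE 0.11, adjusted p = 0.068) and Scn11a from -0.689 (SE 0.0961) to -0.642 (SE 0.1, adjusted p = 0.058). H2-T23 belongs to a family of similar genes, and its count can include reads of a relative. B4galt1, a galactosyltransferase of the Golgi, was the 1 gene that rose, from 47.6 ± 0.21 to 58.6 ± 2.60 CPM (log2 fold change 0.30, SE 0.04, edgeR adjusted p = 0.041), and limma-voom did not call it (adjusted p = 0.052). Its call was also lost in 5 of the 6 fits that left out 1 library (edgeR adjusted p from 0.0642 to 0.28), all but the one without high glucose replicate 2, which raised 31 genes. DESeq2 raised 36. Among the named falls, the calls of Paqr5 (5 of 6 fits), H2-T23 and Scn11a (4 of 6) and Rnf213 (3 of 6) were lost in the same way. Without a threshold for multiple testing, 1233 genes had p under 0.05, of which 723 were lower and 510 higher with emetine. Independent genes with no change would give about 559. Splits of the libraries that mixed the groups gave from 161 to 1330 by the same test, so an excess over chance is not settled. The balance of lower and higher genes depended on the processing: it was 645 lower and 601 higher with upper quartile scaling. By limma-trend on genes with a known length it was 640 lower and 501 higher, and after the length and GC correction 415 lower and 534 higher. In all 31 called genes the 3 emetine libraries lay outside the range of the high glucose libraries. That was so for 17.9% of all tested genes, against the 10% that chance gives on average for 3 against 3. Genes that vary together can move this share in a single split. It was not computed for the other splits, so an excess is not settled here either. The count depended on single libraries: it was 9 without high glucose replicate 1, 154 without replicate 2 and 0 without replicate 3, and 10, 7 and 0 without emetine replicates 1, 2 and 3. The edgeR fits with 0 calls still had 853 and 798 genes at an unadjusted p under 0.05, and DESeq2 on all 6 libraries called 213.

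**Figure D1:**
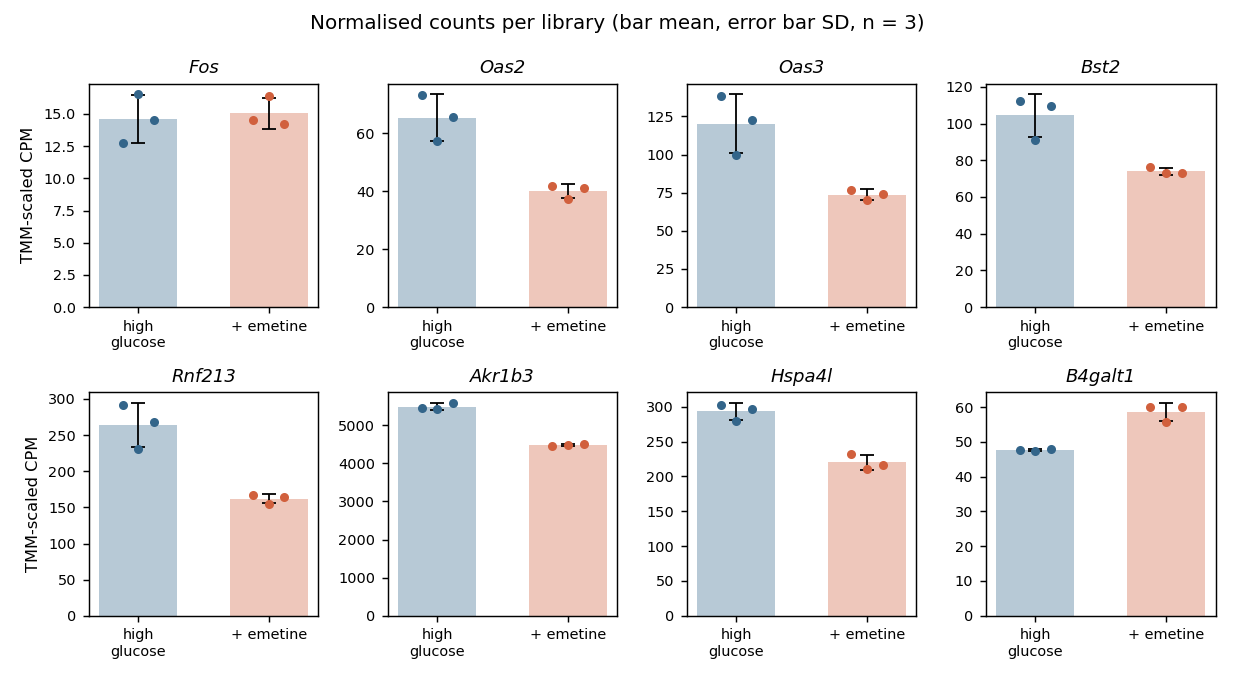
TMM-scaled CPM (y axis, from 0) of 8 genes in high glucose and high glucose with emetine. Bars are means, error bars SD and points the 3 libraries of each group. Fos overlaps between the groups (14.6 against 15.04 CPM), B4galt1 is higher with emetine and the other 6 are lower with no overlap.

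Interferon-stimulated genes, which cells switch on in response to type I interferon, were the most lowered group. All 29 tested members had a fitted value below 0, with a median log2 fold change of -0.87, or 45.4% lower. Over all genes tested, 3 members fell, 0 rose and 26 did not pass. That count of falls was 14 with DESeq2 and 21 with a replicate block. It was 24 without high glucose replicate 2, 1 without replicate 1 and 0 in each of the other 4 fits that left out 1 library. Adjusted over the list alone, 29 of 29 passed. Oas2 fell from 65.4 ± 8.02 to 40.1 ± 2.32 CPM (log2 fold change -0.71, SE 0.09, edgeR adjusted p = 0.022), Oas3 from 120 ± 19.2 to 73.8 ± 3.51 CPM (-0.71, SE 0.10, edgeR adjusted p = 0.038), and Bst2, which tethers budding virus to the cell, from 104 ± 11.5 to 74.1 ± 1.87 CPM (-0.50, SE 0.07, edgeR adjusted p = 0.041). The calls of Oas3 and Bst2 were lost in 5 of these 6 fits and that of Oas2 in 4. The list was lower than the other genes by camera with the preset correlation (adjusted p = 3.62e-18), but not with an estimated correlation (adjusted p = 0.60, correlation 0.91). By fry, which tests the list against no change, the adjusted p was 0.33 for a common direction and 0.127 for mixed directions. The high correlation was visible in the libraries: the list's mean was 4.73, 3.75 and 4.48 log2 CPM in high glucose replicates 1, 2 and 3 and 3.77, 3.37 and 3.51 with emetine, so high glucose replicate 2 lay just under emetine replicate 1. The means of 4.32 ± 0.51 and 3.55 ± 0.20 (SD, n = 3) differed with an exact permutation p of 0.2, 2-sided, where 0.1 is the smallest the design allows. Of the 29 members, 16 had groups that did not overlap. Leaving out high glucose replicate 1 gave a list median of -0.67, and leaving out replicate 2 gave -1.12.

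**Figure D2:**
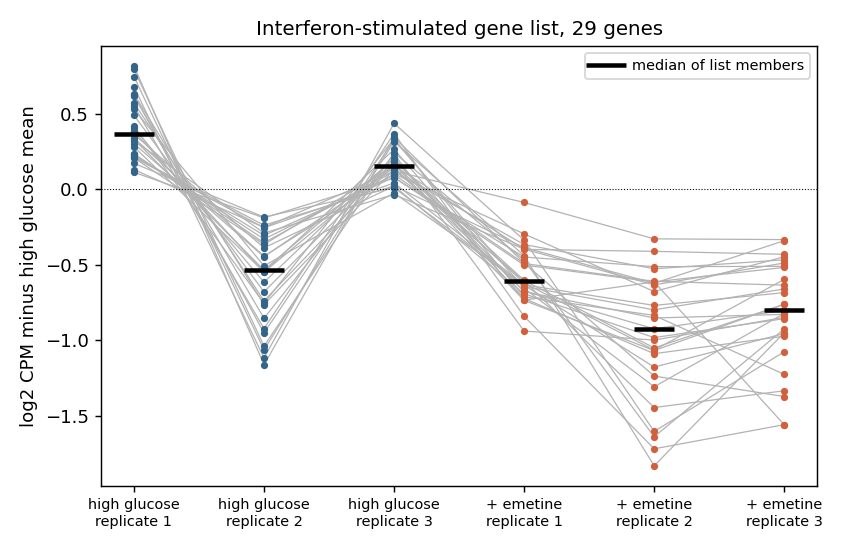
Log2 CPM of each of the 29 interferon-stimulated genes minus its high glucose mean (y axis) in each library (x axis). Points are genes, grey lines join the same gene, and the lines carry no order; black bars are medians. High glucose replicate 2 sits near emetine replicate 1, and the other high glucose libraries sit above all emetine libraries.

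Genes of antigen presentation and co-stimulation were also lower as a list. Whether this was separate from the fall of the interferon list was not tested. The median log2 fold change of the 14 tested members was -0.19, 12 of them had a fitted value below 0, and camera with the preset correlation gave an adjusted p of 3.12e-05 (adjusted p = 0.60 with an estimated correlation). No member passed the edgeR test over all genes. Adjusted over the list alone, 5 were lower: Tapbp (262 ± 22.1 to 212 ± 5.68 CPM) and Tap1, both of peptide loading, the classical class I gene H2-K1, the co-stimulator Cd80, and the immunoproteasome subunit Psmb10. The co-stimulator Cd83 was higher. These names were chosen after their values were seen. B2m, the shared class I light chain and the most abundant member, measured 408 ± 38.3 and 416 ± 4.78 CPM (log2 fold change 0.03, SE 0.06). Its sign was negative without high glucose replicate 2.

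Among heat shock genes, 1 of 15 tested members fell, 0 rose and 14 did not pass. Hspa4l, a heat shock protein of the HSP110 family also known as osmotic stress protein, fell from 293 ± 12.1 to 220 ± 11.3 CPM (log2 fold change -0.41, SE 0.05, edgeR adjusted p = 0.019). The list's median was -0.04 and its camera adjusted p was 0.062. Akr1b3, chosen after its values were seen, encodes aldose reductase, which turns glucose into sorbitol. It was among the most abundant genes and fell from 5487 ± 85.7 to 4483 ± 24.7 CPM (log2 fold change -0.29, SE 0.03, edgeR adjusted p = 0.012), or by 18.3%. Its call and that of Hspa4l were lost without high glucose replicate 3 or emetine replicate 3 (that of Hspa4l also without high glucose replicate 1 or emetine replicate 2), at log2 fold changes of -0.28 and -0.30 for Akr1b3.

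A further 4 groups were higher with emetine by camera with the preset correlation, each by a small amount and with no member past the edgeR test over all genes. The NRF2 antioxidant genes had a median log2 fold change of 0.11 over 25 members, 21 of them above 0 (camera adjusted p = 2.32e-05, adjusted p = 0.60 with an estimated correlation). Adjusted over the list alone, 10 were higher and 0 lower, among them the ferritin subunits: Fth1 measured 3073 ± 193 CPM in high glucose and 3548 ± 139 CPM with emetine (log2 fold change 0.21, SE 0.05, DESeq2 adjusted p = 0.0047), and Ftl1, named after its values were seen, 1849 ± 128 and 2256 ± 114 CPM. Hmox1 and Nqo1, both classical NRF2 targets, measured -0.05 (SE 0.07) and 0.21 (SE 0.33), likewise named afterwards. The nuclear genes of mitochondrial oxidative phosphorylation had a median of 0.06 over 34 members (camera adjusted p = 0.0011, adjusted p = 0.60 with an estimated correlation), with Atp5b at 1564 ± 46.6 and 1600 ± 2.84 CPM. Genes of DNA replication and G1/S had a median of 0.05 over 30 members (camera adjusted p = 0.0025, adjusted p = 0.60 with an estimated correlation), with Pcna at 560 ± 7.48 and 592 ± 13.7 CPM. Lysosome and autophagy genes had a median of 0.06 over 28 members (camera adjusted p = 0.017, adjusted p = 0.60 with an estimated correlation), with the protease Ctsb at 1391 ± 111 and 1625 ± 93.7 CPM (DESeq2 adjusted p = 0.011). After correction for transcript length and GC content the oxidative phosphorylation and lysosome lists no longer passed camera (adjusted p = 0.12 and 0.056, from 0.0016 and 0.022 on the same genes uncorrected). With the longest transcript of any biotype as the length, which was the first choice, the lysosome list passed narrowly (0.0475). The lysosome list also missed the threshold without high glucose replicate 1 (0.25) or 3 (0.090) or emetine replicate 2 (0.052), DNA replication without high glucose replicate 1 (0.058), and oxidative phosphorylation without replicate 2 (0.060).

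**Figure D3:**
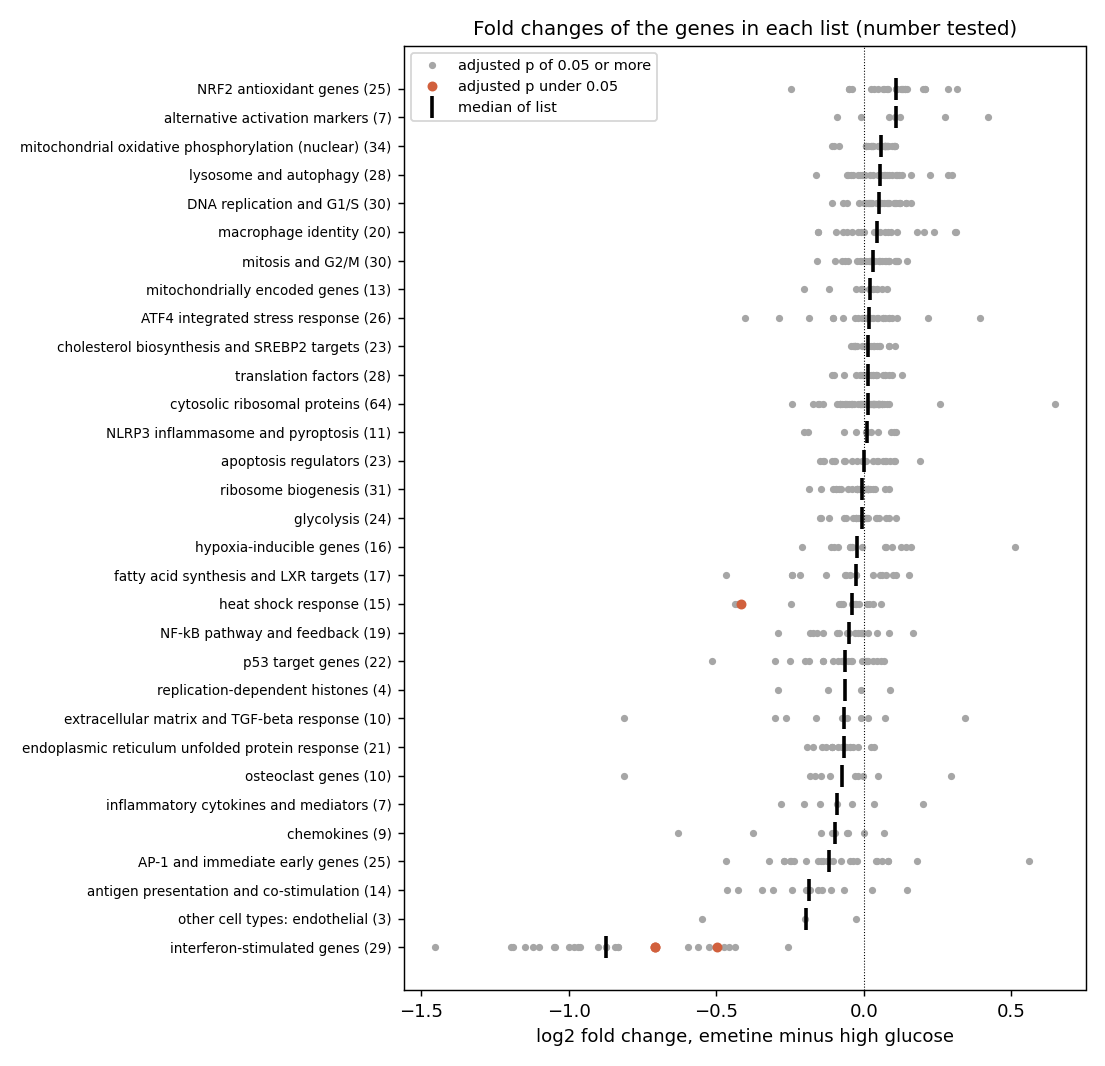
Log2 fold change, emetine minus high glucose (x axis), of every tested gene in the 31 lists with at least 3 tested genes (rows, with the number tested). Points are genes, coloured where the edgeR adjusted p was under 0.05, and black ticks are list medians. The interferon list stands apart with a median of -0.87, and the next lowest median is -0.20.

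In the main fit of all 6 libraries, the remaining lists did not pass camera, and no member of them passed the edgeR test over all genes. With a replicate block, chemokines, alternative activation, the unfolded protein response and p53 targets passed camera, with values given below. Some of the remaining lists, and the heat shock list described above, passed camera when 1 library was left out. These were mitosis (adjusted p = 0.0105) and p53 targets (0.00727) without high glucose replicate 1. Without replicate 2 they were alternative activation (0.0254), macrophage identity (0.0254), the unfolded protein response (1.76e-06) and heat shock (0.00635). The unfolded protein response (0.0125) and heat shock (0.0242) also passed without emetine replicate 1, and p53 targets (0.0144) without emetine replicate 2. Inflammatory cytokines and mediators had 7 genes in the table, with Tnf at 68.2 ± 3.89 and 64.1 ± 1.36 CPM, a median log2 fold change of -0.09 and a camera adjusted p of 0.25. For chemokines the median was -0.10 over 9 genes (adjusted p = 0.25), and the most abundant, Ccl9, measured 394 ± 11.5 and 366 ± 10.2 CPM. The NF-kB list had a median of -0.05 (adjusted p = 0.33), with Sqstm1 at 0.09 (SE 0.08), and the NLRP3 inflammasome list a median of 0.01 and a mean of -0.00792 (adjusted p = 0.71), with Txnip at 0.05 (SE 0.04). Macrophage identity genes had a median of 0.05 (adjusted p = 0.12), with the lysozyme Lyz2 at 2452 ± 241 and 2357 ± 230 CPM. Alternative activation markers had a median of 0.11 over 7 genes (adjusted p = 0.11). Tgfb1 of that list was at 167 ± 7.04 and 166 ± 6.62 CPM, while Cd36 and Trem2, named after their values were seen, were higher when adjusted over the list alone. Osteoclast genes (median -0.07) had Car2 at -0.12 (SE 0.11). The matrix and TGF-beta list (median -0.07, adjusted p = 0.25) held Spp1, which encodes osteopontin, at 2470 ± 148 and 2005 ± 106 CPM (log2 fold change -0.30, SE 0.05, edgeR adjusted p = 0.070). Spp1 passed with DESeq2, and adjusted over the list alone it was the 1 lower member.

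Genes tied to translation were close to level, although emetine acts on the ribosome. Cytosolic ribosomal proteins (64 genes) had a median log2 fold change of 0.01, translation factors (28 genes) 0.01 and ribosome biogenesis genes (31 genes) -0.01, with camera adjusted p of 0.66, 0.28 and 0.30. On genes with a known length the ribosomal protein list turned from up (camera adjusted p = 0.749) to down (0.0559) with the length and GC correction. Rpl4 measured 0.04 (SE 0.04), the elongation factor Eef1a1 -0.01 (SE 0.03) and Npm1 0.03 (SE 0.04). The ATF4 stress response list had a median of 0.02 over 26 genes (adjusted p = 0.70), with Psat1 at 0.01 (SE 0.04). The unfolded protein response list had a median of -0.07, with 19 of 21 members below 0 (adjusted p = 0.062), and its chaperone Hsp90b1 was at -0.11 (SE 0.09). On the genes with a known length and GC content the camera adjusted p went from 0.040 without the correction to 0.0085 with it for this list, from 0.040 to 0.013 for heat shock and from 0.075 to 0.019 for p53 targets. With an estimated correlation, on all genes, none of the 3 passed (adjusted p = 0.73, 0.60 and 0.73). The p53 targets had a median of -0.06 (adjusted p = 0.11 before correction) with Bax at 0.05 (SE 0.05); Cdkn1a, named afterwards, was lower when adjusted over the list alone. Apoptosis regulators were at a median of 0.00247 and a mean of -0.00377, with Mcl1 at 0.03 (SE 0.03). Mitosis genes were at 0.03 (adjusted p = 0.11) with Top2a at -0.02 (SE 0.03), and histones at -0.06 over 4 genes with H1f0 at -0.12 (SE 0.05).

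Metabolic lists other than oxidative phosphorylation did not pass camera on all 6 libraries. Glycolysis had a median of -0.01 over 24 genes (camera adjusted p = 0.71), and Pkm, a pyruvate kinase, measured 7544 ± 94.4 and 7503 ± 251 CPM. Hypoxia-inducible genes were at a median of -0.02 with a mean of 0.03, and Hif1a itself was at 351 ± 24.6 and 304 ± 11.7 CPM (edgeR adjusted p = 0.19, DESeq2 adjusted p = 0.011). Cholesterol synthesis genes were at 0.02, with Fdps at 0.05 (SE 0.06). Fatty acid and LXR genes were at -0.03, with Scd2 at -0.02 (SE 0.07), and adjusted over the list alone Fasn, fatty acid synthase, was lower at 381 ± 16.6 against 450.1 ± 10.4 CPM, named after its values were seen. Mitochondrially encoded genes were at a median of 0.02 and a mean of -0.002, and mt-Co1 measured 15742 ± 224 and 16420 ± 155 CPM.

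Markers of other cell types were scarce. The epithelial, lymphoid and granulocyte, mast cell and erythroid lists had 0 genes in the table. Of the mesenchymal list 1 gene was present, Tagln, at 1.80 ± 0.20 and 1.39 ± 0.09 CPM. Of the endothelial list 3 were present, all with a fitted value below 0 (median log2 fold change -0.20, mean -0.26, camera adjusted p = 0.12). Flt1 measured 56.3 ± 5.44 and 55.3 ± 1.35 CPM, and Pecam1, named after its values were seen, had the lowest value at -0.55. The snoRNA host list had 1 gene in the table, Rack1, at 0.02 (SE 0.05).

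Fold changes fell with transcript length. Across genes, which are not independent replicates, Spearman's rho between the log2 fold change and length was -0.32 over 10384 genes. The median log2 fold change went from 0.04 in the shortest of 5 equal length groups (median length 1311 nt) to -0.05 in the longest (6605 nt), and the longest group held 13 of the 25 lowered genes with a known length. The slope of log2 CPM per doubling of length was -0.000403, 0.04 and 0.01 in high glucose replicates 1, 2 and 3 and -0.01, -0.03 and -0.01 with emetine. These slopes did not overlap, with an exact permutation p of 0.1, 2-sided, the smallest 3 against 3 libraries can give. With length and GC content corrected, limma-trend called 16 genes (1 raised, 15 lowered) against 26 without the correction, and 13 (all lowered) with the first length definition.

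**Figure D4:**
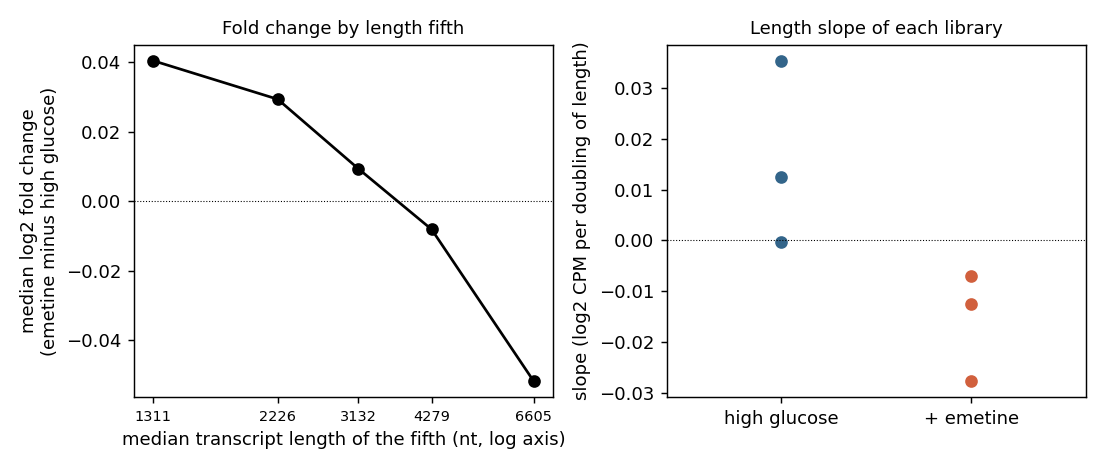
Left, median log2 fold change, emetine minus high glucose (y axis), in 5 equal groups of genes by transcript length (x axis, nucleotides, log scale). Right, slope of log2 CPM on the log2 of length for each library, relative to the mean of all libraries. Fold changes go from 0.04 to -0.05 with length, and each emetine slope lies below each high glucose slope.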

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

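The alternatives named GC content and length, unnamed loci and interferon list were chosen after seeing the data; the others were planned. The 31 calls (30 lowered, 1 raised) stayed within 1.5 times with RLE and upper-quartile scaling, without the unnamed loci and without the interferon list, which is 29 genes fewer. Without that list 24 genes were called (23 lowered, 1 raised), all among the 31. Only 3 of the 31 were list members, so some calls outside the list were lost too. The genes left out were only the list's own members, so the calls left may still include other interferon-induced genes. Both other filters removed no row and so tested nothing. DESeq2 called 213 genes (36 raised, 177 lowered), including all 31, with 4 genes left without an adjusted p. limma-voom called 29 lowered and 0 raised, with 508 higher at an unadjusted p under 0.05. Requiring an absolute log2 fold change of at least 1 left 1 gene. After the length and GC correction 16 genes remained, 15 of them lowered, all among the 26 called by the same test without it. With the longest transcript of any biotype, the definition used first and changed after its results were seen, 13 genes remained (0 raised, 13 lowered), all among those 16. Leaving out each library gave 0 to 154 changed, 0 to 31 raised and 0 to 123 lowered genes. The fits without high glucose replicate 3 or emetine replicate 3 called 0, with 853 and 798 genes at an unadjusted p under 0.05. Each such fit had fewer samples, and the fold changes of the named genes past the threshold kept their direction. The labels give both groups replicate numbers 1 to 3. Over all genes, same-numbered libraries did not deviate together in each case (correlations 0.15, 0.05 and -0.13), and high glucose replicate 2 correlated best with emetine replicate 3 (0.10). Over the interferon list the same-numbered correlations were 0.79, 0.64 and -0.32, against -0.81 and -0.72 for the crossed pairs of numbers 1 and 2. High glucose replicate 3 and emetine replicate 1 gave 0.64 there. These values do not settle whether a number marks a shared culture. With a replicate block, 166 genes were called (20 raised, 146 lowered), including all 31, and 12 lists passed camera, against 6 without it. The 6 added by the block were AP-1 (adjusted p = 0.028), chemokines (0.044), alternative activation (0.0201), unfolded protein response (0.00165), heat shock (0.0146) and p53 targets (0.0146). No list passed with an estimated correlation (0) or by fry for a common direction (0), which tests against no change: the interferon list gave adjusted p of 0.60 and 0.33. Fry for mixed directions passed antigen presentation (adjusted p = 0.00907), NRF2 (0.017) and heat shock (0.0422), but not the interferon list (0.127). Fos ranged from -0.0507 to 0.1395 (log2) when single libraries were left out. The direction of some lists turned between fits. The ribosomal protein list was up in the main fit (camera adjusted p = 0.655) and down without emetine replicate 2 (0.176) or after the length and GC correction (0.0559). Among the named genes, signs that turned all belonged to genes that were not called, at an adjusted p of 0.66 or more. With single libraries left out, these ranged from -0.0357 to 0.0253 for Tgfb1, -0.0293 to 0.103 for B2m, -0.137 to 0.0169 for Lyz2, -0.0177 to 0.0394 for Psat1, -0.000533 to 0.0545 for Rpl4, -0.0324 to 0.0116 for Eef1a1, -0.0302 to 0.0567 for Rack1, -0.0368 to 0.0134 for Pkm, -0.00277 to 0.0967 for Fdps, -0.0876 to 0.0340 for Scd2 and -0.0809 to 0.0564 for Flt1. After the length and GC correction, Rack1 was at -0.0104, Top2a at 0.0103, Scd2 at 0.0146 and Flt1 at 0.0412; with the first length definition Top2a was at 0.00501, Scd2 at 0.0120 and Flt1 at 0.0396. The causes were not tested.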

Other observations

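The fits that leave out 1 library and the count over other splits of the libraries were planned. The osmotic gene list, the permutation test, the length and GC tests and the bound set for the fits that leave out 1 library were chosen, or altered, after the results they bear on had been seen. The altered ones are the length and GC tests, whose transcript definition, margin (1 bootstrap SE) and rule that a list must stay past camera were set after a first run, and the reading of the permutation test as undecided. The bootstrap SE of a list median drew genes of the list, not libraries. It takes the genes as independent and so may understate the error. A test of library scaling was dropped, since a scaling factor moves all genes alike and fixed its outcome. The calls held further genes, all named here after their values were seen and forming no tested group. The interferon list holds only some of the genes that interferon induces. The 27 lowered genes outside it may therefore include others, which was not tested. Ifitm3, which blocks virus entry, fell from 426 ± 34.2 to 319 ± 15.9 CPM, and Mov10, an RNA helicase, from 73.6 ± 3.21 to 53.7 ± 1.14 CPM. Gvin1 and Gvin2, giant GTPases of similar sequence whose reads are hard to tell apart, measured -0.59 and -0.57 (log2), and Ifi27l2a -0.54. The kinases Lrrk2 (101 ± 0.94 to 79.4 ± 0.95 CPM), Prkca (54.4 ± 2.01 to 42.0 ± 2.17 CPM) and Sik2 (80.3 ± 5.41 to 62.1 ± 2.40 CPM) fell as well. Cd5l, a secreted macrophage protein, had the lowest fold change, from 1.87 ± 0.14 to 0.60 ± 0.19 CPM.

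The fall of the interferon-stimulated genes was the largest by median among the tested lists. Transcript length or GC content does not account for it, since the median was -0.84 after correction and -0.87 before, nor does any 1 library, since the median was -0.67 or lower whichever was left out. What stays open is whether cultures differed in interferon activity for reasons other than emetine. The list moved as 1 unit across libraries, and high glucose replicate 2 narrowly overlapped the emetine group (mean 3.746 against 3.765 log2 CPM in emetine replicate 1). With 3 libraries per group, such variation cannot be told apart from an effect of emetine. The exact permutation p was 0.2, but it could not fall below 0.1 in this design, so that test could not decide. An effect of emetine on interferon production or response remains a hypothesis that these files do not test.

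Of the 10 splits of the 6 libraries into 3 and 3, the real one gave the most genes (31, reached by 1 split) and the next gave 2; 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split was not the highest: it gave 1233 genes, and high glucose replicates 1 and 3 with emetine replicate 1 against the other libraries gave 1330.

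Akr1b3 and Hspa4l are both known to rise under osmotic stress, and 40 mM glucose is hyperosmotic to a degree not measured here. A candidate explanation for their fall is a weaker osmotic response with emetine. Among 10 other osmotically induced genes in the table, 9 were below 0, and the median log2 fold change was -0.17 (bootstrap SE over genes 0.07). The estimated correlation of these genes was 0.173. Adjusted over the list alone, 5 passed. These included Nfat5 (-0.26, SE 0.06), the tonicity-responsive transcription factor, and the osmolyte transporters Slc5a3 (-0.23, SE 0.06) and Slc6a12 (-0.14, SE 0.04). Camera gave p = 9.55e-05 with the preset correlation and p = 0.063 with an estimated one, so the hypothesis fits but is not settled. Hspa1a and Hspa1b in that list may share reads. The length and GC correction was not applied to these 10 genes, so the length trend was not tested as a source of their fall. Nfat5 and Slc5a3 were highest in high glucose replicate 2 (655 and 690 CPM), the library with the highest length slope (0.0354). Their other high glucose libraries also lay above all emetine libraries. Length and GC content as the whole cause are argued against by log2 fold changes of -0.32 for Akr1b3 and -0.34 for Hspa4l after correction (-0.265 and -0.347 with the first length definition).

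The fall of fold changes with transcript length may come from RNA integrity or library preparation, and it was tested as a source of the small rises of 4 lists. After the trend was subtracted from the fold changes, the NRF2 median was 0.111 (0.111 before). That of DNA replication was 0.0426 (0.0528 before). Both lists stayed past camera on log2 CPM corrected in each library (adjusted p = 7.69e-05 and 0.00707), so the trend is not the whole of these 2 differences. Neither passed on all genes with an estimated correlation (adjusted p = 0.60 each) or by fry for a common direction (0.231 and 0.331). By fry for mixed directions NRF2 passed (0.017) and DNA replication did not (0.127). Oxidative phosphorylation transcripts have a median length of 1360 nt. For that list the median went from 0.0607 (bootstrap SE over genes 0.0091) to 0.0366 (SE 0.0071) and camera from 0.00161 to 0.122. For lysosome genes it went from 0.0555 (SE 0.0215) to 0.0494 (SE 0.0195) and camera from 0.022 to 0.0559, a small move across the threshold, so both calls ended and for these 2 lists length and a change in the genes cannot be told apart. The first length definition gave medians of 0.109, 0.0488, 0.0395 and 0.0473 for the 4 lists in this order, and under it the lysosome list still passed camera (0.0475), so the end of that call hung on the definition, and a biological cause of the trend was not tested.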
